A study of Arabidopsis thaliana with 8 samples.

How the data were processed

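Total RNA of developing Arabidopsis leaves was labelled with biotin and hybridised to 8 ATH1 arrays, per the labels. The deposited values are probe set intensity on a linear scale, made by the authors with MAS5, per the submitters' processing notes, which give no version. MAS5 combines the probe pairs of a probe set into 1 signal and scales each array. In the deposited values the mean of each array, after trimming 2% at each end, was 100 units, and 0 values lay at or below 0. Detection calls were not used here, so a low signal cannot be told from absence of the transcript, and scaling to a common mean hides any change shared by all transcripts. Other steps before deposition are not given in the sources used here.

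The 2 groups of 4 arrays were set from the labels before the data were examined, as were the test, the rule for named genes, the gene lists and the alternatives, except where a setting is said to have been chosen afterwards. The 4 arrays whose treatment text names elevated growth form the elevated group. Not-elevated replicate 1 has another title code than the other 3 of its group and is described by a letter in place of the word control. It stands in that group because its labels put it at 0 h and do not name elevated CO2, and the calls, the named genes and the gene lists were also computed without it. The description field of all 8 arrays calls the atmosphere normal, and the treatment text was followed for the elevated group; that of elevated replicate 4 says elevated without naming CO2. The CO2 level of 750 ppm and the 24 h of adjustment stand only in the label of elevated replicate 1. The highest correlation between 2 arrays was 0.986, and each was counted as 1 sample.

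After 64 control probe sets were left out, 22746 remained, and 15296 with a mean signal of at least 20 units over all 8 arrays were tested. Signals were transformed as log2(signal + 10), and the groups were compared with limma's lmFit and eBayes with a trend of the variance on signal (limma 3.58.1 in R 4.3.3). P-values are two-sided and were adjusted by the Benjamini-Hochberg method at 0.05. Because of the pseudocount of 10, a log2 difference understates the change of a dim gene. Errors are SDs over 4 arrays for signals and the fit's SEs for log2 differences.

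Probe sets were named through the platform's gene table and updated by gene number through the RefSeq gene table of TAIR10.1. The files name no genome build, so coordinates are not used here. Of 22746 probe sets, 13513 name 1 gene, 503 several and 8730 none in the tables used here, and 13436 of the 13513 matched a locus. Probe sets with several genes or none were tested but not named as genes. The 8518 tested probe sets with 1 gene stand for 8429 genes, and the brightest probe set was used where a gene had several.

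The named genes are, by the rule, the up to 10 largest rises and 10 largest falls past the threshold among probe sets with 1 gene whose groups do not overlap, and the 2 members of each list with the smallest p. Falls that met it numbered 8. The 33 gene lists cover photosynthesis, carbon and nutrient metabolism, defence, stress, growth and markers of cell types. Of the 734 loci in 30 of them, 111 are named on the array by the gene tables used here and 96 were tested, so most lists are represented by few members. A list's result covers only those members, which need not stand for the whole pathway. The other 3 were rules on names. Plastid genes were taken by their chromosome and mitochondrial genes by chromosome or symbol, because their locus tags did not have the form the rule assumed, and the ribosomal rule matched 0 probe sets. Lists with at least 3 tested members, 21 in all, were tested with limma's camera at a preset correlation of 0.01, with the estimated correlation and limma's fry as alternatives. Fry tests whether a list's genes move on balance one way and does not compare them with other genes.

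The test was checked on simulated arrays with the means and spreads of the 15296 probe sets, 5 times with 100 probe sets changed at each size. It recovered 58.8% of those changed 1.5-fold and 92.0% of those changed 2-fold, and 5.39% of its calls were false. Camera found 5 of 5 sets of 8 genes shifted by 0.5 on the log2 scale and 0 of 20 unshifted sets. Simulated noise was independent between probe sets and alike for all arrays, so these checks do not cover correlated genes or arrays of unequal quality. The 3 lists called below had estimated correlations of 0.155 (glucosinolate synthesis), 0.335 (abscisic acid, drought and cold) and 0.436 (light reactions).

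Alternatives were quantile normalization, scaling of each array to a common median, pseudocounts of 1 and 50, no filter and a mean signal of at least 50 units, eBayes without the trend, array weights, the replicate number as a block and each array left out in turn. Leaving out both replicate 1 arrays, and camera with the estimated correlation without not-elevated replicate 1, were added after the data were seen. Results on some genes are not reported here. No batch or scan date is given in the sources used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.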

Results

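Transcripts of developing leaves of Arabidopsis thaliana, accession Col-0, were measured on 8 ATH1 arrays, an Affymetrix design in which each probe set reads 1 transcript or a few related ones. All samples were taken at 0 h from leaf insertions 19 to 21. Plants grew at 20 °C, 50% humidity and 10 h of light. In 4 samples the plants had been grown in elevated CO2, which the label of elevated replicate 1 gives as 750 ppm, with 24 h of adjustment in a cuvette before harvest. The general growth description, shared by all 8 samples, calls the atmosphere normal, so the elevated group rests on the separate treatment text, which for elevated replicate 4 says elevated without naming CO2. The labels of the other 4 samples do not name elevated CO2, and these form the not-elevated group. Not-elevated replicate 1 carries another title code than the remaining 3 of its group, and its code is not that of the elevated arrays either. It was placed there because its labels put it at 0 h and do not name elevated CO2, although its description has a letter where the other 3 have the word control. Each array held 22810 probe sets with a trimmed mean signal of 100 array units, and between 66.1% and 69.7% of the signals per array reached 20 units. The number of arrays limits the precision of each value. The labels do not say that replicates came from separate plants, so the p-values measure the spread between these samples, which may be technical.

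The 8 arrays were alike, and the groups were only slightly apart. Pearson's r across probe sets, which are not independent replicates, averaged 0.980 over the 12 pairs within groups (0.969 to 0.986) and 0.976 over the 16 pairs between groups (0.968 to 0.982). The first principal component held 25.5% of the variance. Elevated replicate 3 correlated more with the not-elevated arrays (mean r 0.981) than with its own group (0.977). Elevated replicate 1 had the lowest mean correlation with its own group, 0.973.

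The comparison asks which transcripts of young leaves differ at 0 h between plants grown in elevated CO2 and plants not labelled so. BCAT4 (AT3G19710), an aminotransferase that starts the lengthening of methionine for aliphatic glucosinolates, rose from 34.1 ± 6.25 units in the not-elevated group to 76.8 ± 11.2 in the elevated group (SD, n = 4 each). CSLA01 (AT4G16590), of the cellulose synthase-like family, rose from 30.5 ± 5.37 to 69.7 ± 12.2 units. HYH (AT3G17609), a bZIP transcription factor of light signalling and the homolog of HY5, fell from 154 ± 13.1 to 86.1 ± 27.4 units. FDH (AT5G14780), the formate dehydrogenase gene, fell from 147 ± 24.6 to 80.8 ± 19.7 units. On the log2(signal + 10) scale these differences were 0.98 ± 0.13 (SE) for BCAT4, 0.97 ± 0.13 for CSLA01, -0.80 ± 0.15 for HYH and -0.80 ± 0.15 for FDH. Their limma adjusted p-values were 0.0139, 0.0139, 0.0476 and 0.0489. In each of these genes the signals of the 2 groups did not overlap, as the rule for naming genes required. HYH read 127.1 units in elevated replicate 3 against 70.7 to 75.1 in the other elevated arrays.

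Other named genes rose as well. AT3G15450, of the aluminium-induced YGL and LRDR motif proteins, rose from 193 ± 21.4 to 376 ± 77.5 units. AT4G27450, which belongs to the same protein class, rose from 97.95 ± 5.07 to 176 ± 43.8 units. AT5G19120, of the aspartyl protease family, rose from 112 ± 10.5 to 211 ± 36.3 units. The thionin gene THI2.1 (AT1G72260), which responds to jasmonate, rose from 48.0 ± 10.5 to 91.8 ± 13.9 units. AT2G31790, listed beforehand as the glucosinolate glucosyltransferase UGT74C1, rose from 127 ± 9.59 to 205 ± 31.6 units. AT2G39400 (log2 difference 0.79), AT1G56220 (0.63) and AT1G30820 (0.63) completed the 10 largest named rises, with limma adjusted p-values from 0.0139 to 0.0488 over the 10.

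Among the falls, AT1G19960 went from 155 ± 26.6 to 66.4 ± 32.3 units, a log2 difference of -1.18 ± 0.21 (SE). The leucine-rich-repeat receptor kinase genes AT1G35710 and AT4G08850 fell as well, from 74.8 ± 14.2 to 41.9 ± 1.67 units and from 146 ± 19.7 to 88.9 ± 4.27 units. AT5G19240 (log2 difference -0.57), AT3G55520 (-0.56) and AT1G48100 (-0.52) also fell, and the limma adjusted p-values of these 6 genes lay between 0.0273 and 0.0489. The remaining named rises were AT1G78560 (0.52), AT5G16550 (0.43) and ACT11 (0.43), named here after their values were seen.

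**Figure D1:**
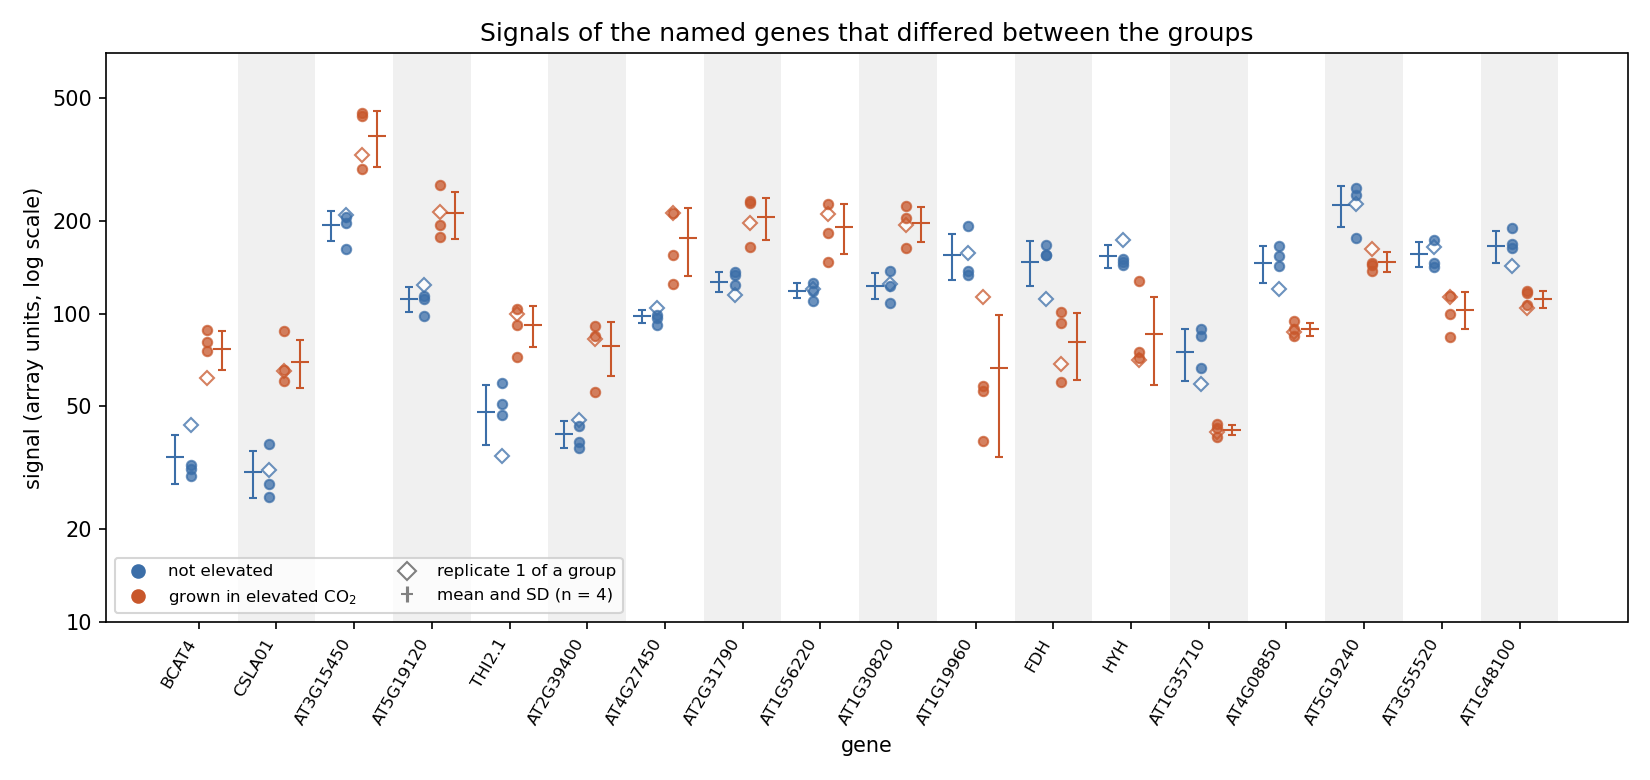
Signal in array units on a log axis for the 18 named genes that differed, with the not-elevated arrays in blue and the arrays of plants grown in elevated CO2 in orange. Each symbol is 1 array, open diamonds are replicate 1 of a group, and bars are the mean and SD (n = 4). The 2 groups do not overlap in any of these genes, as the rule for naming them required.

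Of 15296 probe sets tested with limma, 48 passed an adjusted p of 0.05, 30 higher and 18 lower in the elevated group. An unadjusted p under 0.05 was reached by 1703 probe sets, where chance gives 765 on average. Other ways to split the 8 arrays 4 against 4 gave 290 to 1533 such probe sets. The highest came from the split that exchanges not-elevated replicate 1 with elevated replicate 3. The groups did not overlap in 6.11% of the tested probe sets, where chance gives 2.86% on average, and in 47 of the 48. The 48 differed by 0.39 to 1.81 on the log2(signal + 10) scale (median 0.75), 7 of them by more than 2-fold on that scale and 11 by the ratio of mean signals. Of the 48, 21 name 1 gene, 13 higher and 8 lower. On the log2(signal + 10) scale the largest rise and the largest fall were in probe sets for which the tables used here give no gene, singled out after their values were seen. The probe set with the largest rise read 229 ± 38.0 and 744 ± 295 units in the not-elevated and elevated groups, and the one with the largest fall read 668 ± 216 and 201 ± 134 units (SD, n = 4 each).

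The number of probe sets past the threshold depended on single arrays. It was 131 without not-elevated replicate 1, 77 without elevated replicate 3, 29 without elevated replicate 1, 12 without elevated replicate 2, 9 without not-elevated replicate 2, 8 without elevated replicate 4 and 7 without not-elevated replicate 4. Without not-elevated replicate 3 limma called 0, with 1395 probe sets at an unadjusted p under 0.05. Of the 18 named genes, 15, 16, 6, 4, 3, 3, 3 and 0 stayed past the threshold in these 8 fits, in the same order. BCAT4 and AT5G19120 stayed past it in 7 of the 8, missing it without not-elevated replicate 3 (adjusted p = 0.0556 for both). HYH stayed past it in 1 of the 8, the fit without elevated replicate 3. With both replicate 1 arrays left out, a setting chosen after the data were seen, 144 probe sets passed, 41 of them among the 48, and 15 of the 18 named genes.

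Settings of the analysis moved the calls too. All 18 named genes lost the threshold without a filter on low signals, and 15 of the 18 without a trend of the variance on signal. Quantile normalization kept 10 of the 18, scaling to a common median 13, and a pseudocount of 1 kept 10. With a pseudocount of 50 the log2 differences of dim genes were smaller, 0.59 for BCAT4 and 0.57 for CSLA01.

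**Figure D2:**
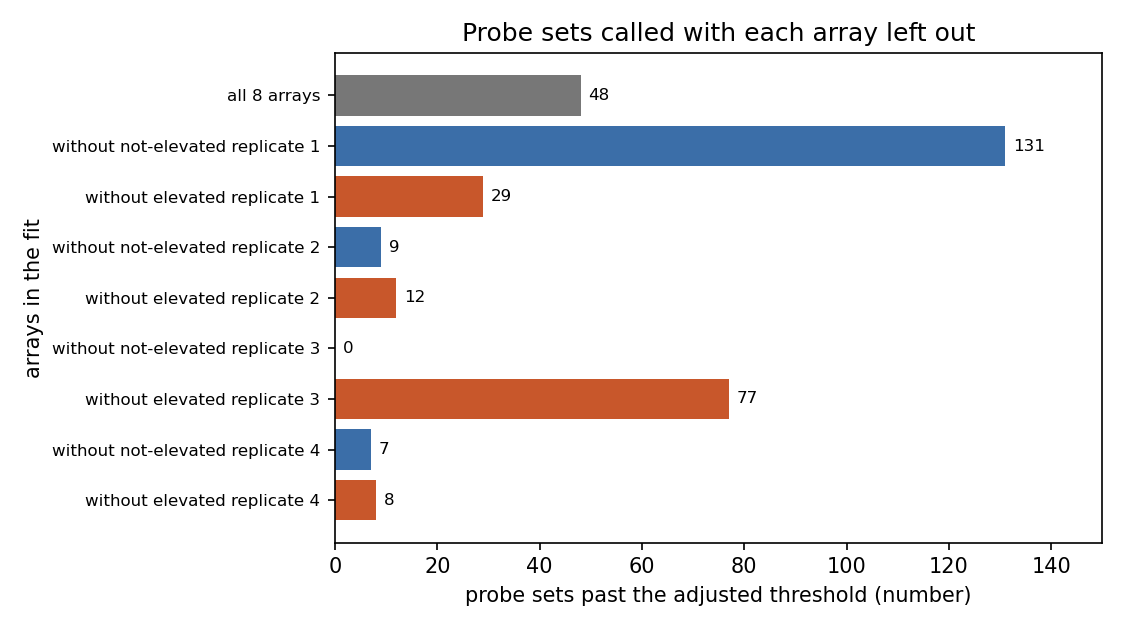
Number of probe sets past the adjusted threshold with all 8 arrays (grey) and with each array left out (blue, a not-elevated array left out; orange, an elevated array left out). The bars start at 0 and run from 0 without not-elevated replicate 3 to 131 without not-elevated replicate 1.

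In the glucosinolate list 2 of the 3 tested members were higher in the elevated group. BCAT4 and AT2G31790 rose, and UGT74B1, which acts in the core of glucosinolate synthesis, read 249 ± 64.3 and 212 ± 26.3 units (log2 difference -0.19, not past the threshold). The same 2 members passed when adjusted over the list alone. The list median was 0.64, with camera's adjusted p = 0.00515, against adjusted p = 0.367 with an estimated correlation and 0.0589 with fry.

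In the abscisic acid, drought and cold list the 4 tested members were each lower. None of them passed over all probe sets tested, and 2 passed when adjusted over the list alone. COR15A, a cold-regulated chloroplast protein gene, read 72.3 ± 20.3 and 38.8 ± 12.5 units (log2 difference -0.75 ± 0.19 SE), and its relative COR15B read 112 ± 14.5 and 75.7 ± 13.0 units (-0.52 ± 0.12). The list median was -0.36, with camera's adjusted p = 0.00515, against adjusted p = 0.367 with an estimated correlation and 0.131 with fry. COR15B passed the threshold without elevated replicate 3 (log2 difference -0.61, limma adjusted p = 0.0459).

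The 8 tested genes of the photosynthetic light reactions were each higher in the elevated group by a small amount, and none passed the threshold. PSBY, of photosystem II, read 2312 ± 226 and 2687 ± 247 units, and LHCB4.3, a light-harvesting protein gene, 486 ± 22.4 and 545 ± 19.9 units. The list median was 0.15, with camera's adjusted p = 0.0121, against adjusted p = 0.776 with an estimated correlation and 0.398 with fry. With quantile normalization 6 of the 8 were higher, the median was 0.06 and the adjusted p = 0.430. The call also ended without not-elevated replicate 2 (adjusted p = 0.165), not-elevated replicate 4 (0.0577) or elevated replicate 4 (0.0656).

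The Calvin-Benson and photorespiration lists, each with few of its 24 fixed loci tested, were not past the threshold. The 4 tested Calvin-Benson genes and the 6 of photorespiration were each higher in the elevated group with all 8 arrays, with medians of 0.13 and 0.10 (camera's adjusted p = 0.216 and 0.123, and 0.776 for both with an estimated correlation). With quantile normalization the medians were 0.029 and 0.064 and 3 of the 4 Calvin-Benson genes were higher, and without not-elevated replicate 4, 5 of the 6 of photorespiration were. Without not-elevated replicate 2 the medians were 0.054 and 0.068, the lowest with 1 array left out. Without not-elevated replicate 1 both lists passed, with medians of 0.19 and 0.16 (adjusted p = 0.0408 and 0.0090), against adjusted p = 0.412 for both with an estimated correlation, a setting chosen after the data were seen. Sucrose metabolism and sugar transport had a median of 0.12 over 3 genes (adjusted p = 0.681), from 0.011 without not-elevated replicate 3 to 0.19 without elevated replicate 3. Of the starch genes, 2 of synthesis had a median of 0.05 and 2 of breakdown a median of -0.13, too few for a list test. In the sugar-starvation list, AKINBETA1, a subunit of the SnRK1 kinase, read 79.6 ± 12.2 and 110 ± 17.44 units (log2 difference 0.42, limma adjusted p = 0.217) and was the 1 of 5 members that passed when adjusted over the list alone. The median of that list was -0.0025 and its mean 0.10, with camera's direction up (adjusted p = 0.471). With 1 array left out that median ran from -0.025 without not-elevated replicate 1 to 0.056 without elevated replicate 3.

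In the flavonoid list, DFR, which acts in anthocyanin synthesis, read 130 ± 34.1 and 210 ± 69.5 units (log2 difference 0.62, limma adjusted p = 0.257), and UGT78D2 333 ± 25.9 and 290 ± 32.2 units. The median over its 6 genes was 0.31 (camera's adjusted p = 0.344), and with 1 array left out it ran from 0.096 without not-elevated replicate 1 to 0.43 without not-elevated replicate 4. The jasmonate list had 3 tested members, of which THI2.1 rose, also when adjusted over the list alone (median 0.11, camera's adjusted p = 0.0891). That median ran from 0.021 without elevated replicate 4 to 0.38 without elevated replicate 3. The 2 sulfur genes, AT1G04770 and BGLU28, read -0.34 each on the log2 scale, and AT1G04770 passed when adjusted over the list alone. With 1 array left out BGLU28 ran from -0.18 without elevated replicate 2 to -0.49 without elevated replicate 1. PPDK, the single tested senescence gene, read 48.0 ± 24.96 and 16.7 ± 3.07 units (log2 difference -1.002, limma adjusted p = 0.170), and -1.33 without not-elevated replicate 1 (adjusted p = 0.00666). GI, the single tested clock gene, read 50.6 ± 5.98 and 32.9 ± 8.33 units (-0.51, adjusted p = 0.185).

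Among the 6 heat shock genes, Fes1A read 243 ± 41.3 and 162 ± 49.6 units (log2 difference -0.58, limma adjusted p = 0.190), and passed without elevated replicate 3 (-0.76, adjusted p = 0.0224). The list median was 0.08, its mean -0.0006 and camera's direction up (adjusted p = 0.681). The antioxidant list had a median of 0.04 over 6 genes (adjusted p = 0.681), from 0.0089 without elevated replicate 4 to 0.10 without elevated replicate 1. Salicylate and pathogen defence (0.18) and touch and rapid stress (-0.16) had 1 tested gene each.

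Growth and cell-type lists did not pass. Of 7 cell wall expansion genes, EXPA15 read 208 ± 32.2 and 150 ± 7.76 units and EXGT-A3 263 ± 22.4 and 327 ± 27.3 units, with log2 differences of -0.44 and 0.30. Both passed when adjusted over the list alone and neither over all probe sets (list median 0.16, camera's adjusted p = 0.469). Medians were 0.15 for 3 cell cycle genes (adjusted p = 0.587), 0.18 for 3 auxin and shade genes (0.508), -0.13 for 4 meristem and young leaf markers (0.469) and 0.09 for 3 epidermis and trichome markers (0.681). With 1 array left out, the cell cycle median ran from 0.043 without elevated replicate 1 to 0.23 without elevated replicate 4, the cell wall median from 0.093 to 0.22, the auxin and shade median from 0.104 to 0.25 and the meristem median from -0.19 to -0.073. The 3 stomatal genes had a median of 0.04 and a mean of -0.03, with camera's direction down (adjusted p = 0.702). The 3 root markers had a median of -0.09 (adjusted p = 0.681) and the xylem marker 0.22. The 4 reference genes had a median of -0.04 (adjusted p = 0.681).

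Of 69 plastid-encoded genes, 34 were higher and 35 lower, and none passed. The photosystem genes psbD and psaB read 0.38 and 0.26 on the log2 scale (limma adjusted p = 0.214 and 0.267), and psaB read 0.12 with quantile normalization. The median of the list was -0.0042 and its mean -0.0064, with camera's direction up (adjusted p = 0.681). The 7 mitochondrion-encoded genes had a median of 0.10 (adjusted p = 0.469). Nitrogen assimilation, phosphate starvation and cytosolic ribosomal proteins had 0 genes tested here.

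**Figure D3:**
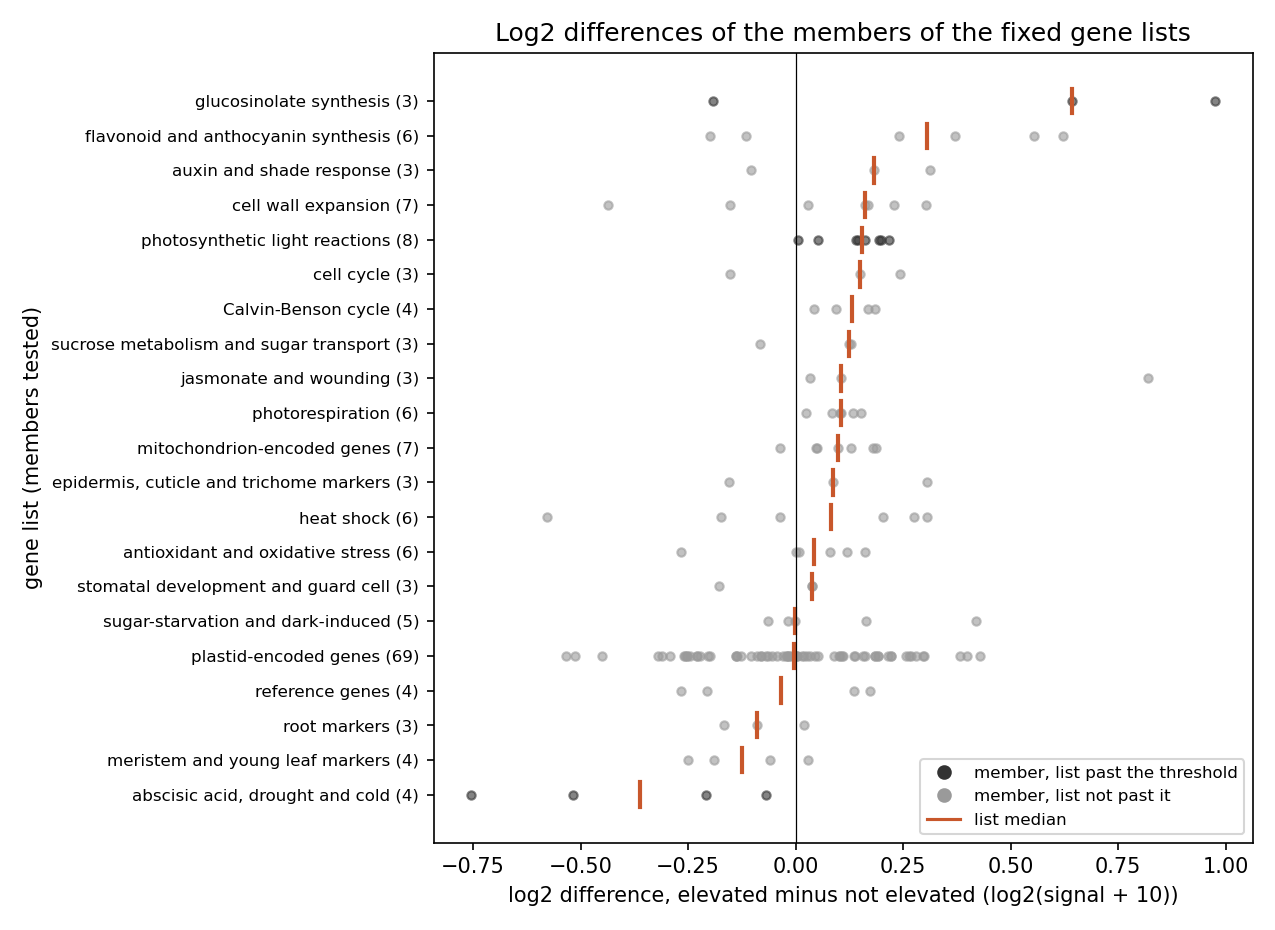
Log2 difference between the groups, elevated minus not elevated, for each tested member (points) of the 21 gene lists with at least 3 tested members, with the list median in orange. Dark points belong to the 3 lists past camera's threshold, whose medians are 0.64, 0.15 and -0.36.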

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

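A value was picked out where the highest or lowest of the 4 arrays of a group lay far from the other 3 by Dixon's test. Among named genes 86 groups were tested and 2 picked out, where chance gives 4.3 for groups not picked by their values. The named genes were picked by their p-values, so that rate is only a guide, and the number of 2 does not by itself stand out. HYH read 127.1 units in elevated replicate 3 and 70.7 to 75.1 in the other elevated arrays. Fes1A read 235.9 units in the same array and 133.6 to 142.8 in the others.

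Among 20 groups of array measures, 3 were picked out. The 25S ribosomal RNA control read 600.2 units in not-elevated replicate 2 and 73.4 to 146.5 in the other not-elevated arrays. The bioD spike control read 790.3 units in not-elevated replicate 1 and 434.7 to 442 in the others. The middle ubiquitin control probe set read 763.5 units in not-elevated replicate 1 and 606.8 to 627.7 in the others.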

How the results depend on the processing

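Leaving out both replicate 1 arrays, and the estimated correlation without not-elevated replicate 1, were chosen after the data were seen; the other settings were fixed before the data were examined. Against 48 calls (30 higher, 18 lower), quantile normalization gave 30 (9 lower), scaling to a common median 33 (10 lower), a pseudocount of 1 gave 28 (7 lower), no filter 1 (0 higher, 1 lower, none shared with the 48), no trend 9 (7 higher, 2 lower), array weights 132 (62 higher, 70 lower) and both replicate 1 arrays out 144 (61 higher, 83 lower). With 1 array left out the count ran from 0 (without not-elevated replicate 3) to 131 (without not-elevated replicate 1), the higher calls from 0 to 57 and the lower from 0 to 74. The other fits gave 77 without elevated replicate 3, 29 without elevated replicate 1, 12 without elevated replicate 2, 9 without not-elevated replicate 2, 8 without elevated replicate 4 and 7 without not-elevated replicate 4. The fit with 0 calls by limma had 1395 probe sets at an unadjusted p under 0.05. The cause was not tested, except that these fits had fewer arrays and the unfiltered fit more probe sets. The 18 named genes kept their direction in all settings. With arrays left out this follows from the naming rule, which required groups without overlap. These genes lost the threshold in 94 of 144 left-out values and 63 of 180 others. Of the other named genes, 3 of 200 left-out values and 1 of 244 others passed.

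Replicate numbers did not pair the arrays: own-number correlations of deviations were -0.08, -0.18, -0.04 and -0.07, and 0 arrays correlated best with their own number. With the number as a block 50 probe sets were called, 32 of them among the 48.

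Of 21 lists 3 were called, 2 to 5 with 1 array left out (5 without not-elevated replicate 1), 6 with both replicate 1 arrays out, and 0 with the estimated correlation or fry, where 2 and 3 lists had an unadjusted p under 0.05. The medians of the 3 lists, which these tests leave as they are (0.64, -0.36 and 0.15), had adjusted p = 0.367, 0.367 and 0.776 with the estimated correlation and 0.0589, 0.131 and 0.398 with fry. Left-out medians ran from 0.58 to 0.74 for glucosinolate synthesis, from -0.47 to -0.32 for abscisic acid, drought and cold, and from 0.12 to 0.19 for the light reactions. The light reactions had a median of 0.056 with quantile normalization (adjusted p = 0.430), and their call also ended without not-elevated replicate 2 (0.165), not-elevated replicate 4 (0.0577) or elevated replicate 4 (0.0656). With the estimated correlation and without not-elevated replicate 1, camera called 0 lists, with 1 at an unadjusted p under 0.05 (glucosinolate synthesis, 0.0269), and the medians of the 3 lists were 0.60, -0.36 and 0.19 (adjusted p = 0.412 each). Photorespiration also passed with array weights (adjusted p = 0.0402).

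Camera's direction turned only in lists that were not called, with these medians. Plastid-encoded genes had -0.048 with quantile normalization, -0.071 without elevated replicate 3 and -0.057 without not-elevated replicate 4, in a left-out range of -0.071 to 0.032; with both replicate 1 arrays out the list passed (median 0.064, adjusted p = 0.0179). Heat shock had -0.11 with the stricter filter, 0.019 without elevated replicate 3 and -0.027 without not-elevated replicate 4 (range -0.027 to 0.15). Stomatal genes had 0.097 without not-elevated replicate 1, with the preset and the estimated correlation (range -0.071 to 0.097). Reference genes had 0.0065 without elevated replicate 1, 0.013 without not-elevated replicate 3 and -0.0063 with both replicate 1 arrays out (range -0.095 to 0.013). Mitochondrion-encoded genes had 0.030 without elevated replicate 1 and -0.095 with both out (range 0.013 to 0.17). Epidermis markers had -0.075 without elevated replicate 3 (range -0.075 to 0.24), root markers 0.0062 without elevated replicate 4 (range -0.13 to 0.0062) and cell cycle genes -0.034 with both out. The cause was not tested. Signals near 20 units lie close to background, and a pseudocount of 10 shrinks their differences.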

Other observations

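The tests of the other splits, of array position and of dim against bright probe sets were set before their results were seen; those of scaling, RNA integrity, array weights, noise independent between probe sets (with arrays held out in pairs) and gene families were chosen after their results or related values had been seen.

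Genes that share a symbol stem were tested as families, to ask whether whole families moved together. Of 18 families with at least 8 tested genes, 0 passed camera's threshold with both the preset and the estimated correlation, so a shift of whole families was not shown. With the preset correlation alone, 3 families had an unadjusted p under 0.05 by limma's camera.

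The 48 calls are more than the other splits of the arrays gave. Only 1 of 35 splits, the real one, gave 48, and the highest other gave 29, so chance in the grouping is argued against. The 48 were picked as deposited and array medians lay between 42.4 and 46.3 units, so their sizes cannot decide on array scaling. With quantile normalization 30 probe sets were called, and with scaling to a common median 33. The median difference of the 48 in their own direction was 0.7542 at the lowest under these scalings, against 0.7546 as deposited. RNA integrity was judged by the 3' to 5' ratios of the actin, GAPDH and ubiquitin controls. With the mean of the 3 standardised ratios as a covariate, that median was 0.7331. The 48 were picked for their group difference and the groups overlapped in all 3 ratios, so this median had little room to fall. With the covariate 47 probe sets were called, 32 of them among the 48, so the number of calls did not hang on these ratios. Each mean ratio was higher in the elevated group, and whether RNA integrity contributed stays open. Growth in elevated CO2 may account for the calls, and so may any difference of growth room or handling between the groups, which was not tested. In each replicate the not-elevated array has the lower running number in its title and the elevated array the higher. An order of handling, if these numbers give one, cannot be told apart from the groups.

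Not-elevated replicate 1, whose title code differs, holds down the number of calls, 131 without it and 48 with it. With each array held out in turn and placed on the 100 probe sets that best separate the other 7, its median position was 0.6197 between the other not-elevated arrays (0) and the elevated ones (1), against 0.04 to 0.12 for the rest of its group and 0.49 to 1.00 for the elevated arrays. Noise independent between probe sets is argued against, since, held out together with another not-elevated array and placed on the same 100 probe sets, it lay nearer the elevated side than its companion in 84, 94 and 79 of them, where equal chance gives 50 and the 3 pairs without it gave 41 to 58. Its title code is that of neither group, and what the code stands for is not given in the sources used here. By the running number in the titles it is placed as the other not-elevated arrays are, with the lower number of its replicate. A title cannot show a mix-up of samples. A sample of elevated-grown leaves under a wrong label may be a cause, as may a noisier array. Array weights gave 132 calls with all 8 arrays, but they lower any array far from its assigned group. They therefore cannot tell these causes apart, and they lowered elevated replicate 1 (weight 0.510) more than this array (0.705). The split with 29 calls exchanges this array with elevated replicate 3 (position 0.49), and PPDK read 17.0 units here, 38.7 to 69.5 in the rest of its group and 14.0 to 21.1 in the elevated arrays, while HYH (172.9 units, against 143.8 to 150.1 and 70.7 to 127.1), THI2.1 (34.45, against 46.97 to 59.7 and 72.3 to 103.4) and the middle ubiquitin control (763.5, against 606.8 to 627.7 and 394.9 to 561.4) lay beyond its own group on the side away from the elevated arrays; the array was kept in its group throughout.

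Elevated replicate 1 stands apart from the other 7 arrays, with a residual SD of 0.219 against 0.148 to 0.191. A background offset at low signals may contribute, since its median deviation was 0.1751 higher over the dimmest probe sets (the lowest 25%) than over the brightest 25%, where the next size was 0.1135. Lower RNA integrity may contribute as well, since it had the highest of 8 ratios in 3 of 3 controls, 2.29 for actin, 1.25 for GAPDH and 2.23 for ubiquitin. Both stay open, and no biological explanation was tested.

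The middle ubiquitin control probe set read 653 ± 74.0 units in the not-elevated and 449 ± 77.5 in the elevated group (SD, n = 4 each), without overlap as deposited or under either scaling. It was singled out after its values were seen, as the 1 of 10 array measures in which the groups did not overlap.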
